A study of Mus musculus with 12 samples.

How the data were processed

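Gene expression was measured by stranded mRNA sequencing in 12 tumour samples, 3 in each of 4 groups, and the group and replicate number of each came from the submitters' sample labels. Libraries were made with a TruSeq stranded mRNA kit and sequenced as read pairs on a NovaSeq instrument, per the labels' protocols. The labels give no animal, batch, dose or harvest time for a sample. The deposited values are raw counts per gene, one library per file. They were made by featureCounts 1.6.0 over exons grouped by gene, with read pairs counted as fragments and the reverse strand setting, on GRCm39 with the GENCODE M33 annotation, per the file headers. STAR 2.7.9a, FastQC 0.11.8, edgeR and limma are named per the submitters' processing notes. Because counting used the strand, reads of antisense neighbours were kept apart.

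Every file held the same 56884 genes. Symbols were taken from the GENCODE M21 annotation by gene identifier, which named 51948 of them (91.3%) and covered at least 99.041% of the counts of each library, and coordinates were kept as in the authors' files. Mitochondrial genes took 1.163% to 1.623% of the counts and the 10 most abundant genes 4.072% to 4.714%. Members of near-identical families, among them the granzyme, Ifit, Gbp, Tgtp, Mcpt and Klra genes, can share reads, so their single values are uncertain. The MHC genes and Ighg2c are also uncertain, because they vary between mouse strains and the reference genome is of one strain.

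Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 17757, and libraries were scaled by TMM. One model with the 4 groups was fitted to all 12 libraries, with a common biological coefficient of variation of 0.205 and 8 residual degrees of freedom, and contrasts were tested by the robust quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of genes are from this test unless another tool is named. The contrasts were each treated group against control, RT_FAP41BBL against RT and against FAP41BBL, and the interaction, which is the change with radiotherapy in the presence of the agonist minus the change without it. Scores are means of log2 CPM over a list with a prior count of 2.

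Gene lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01, and again with a correlation estimated for each list. The lists were also tested by fry, which asks whether a list moves on balance in one direction. The 29 lists were T cells, cytotoxic effectors, checkpoint and costimulation, regulatory T cells, B and plasma cells, type I interferon response, interferon-gamma response, MHC class I presentation, MHC class II presentation, dendritic cells, macrophages and monocytes, neutrophils, mast cells and eosinophils, fibroblasts, TGF-beta targets, endothelial cells, epithelial tumour cells, G2/M cell cycle, G1/S and DNA replication, p53 targets, hypoxia and glycolysis, T cell and monocyte chemokines, inflammatory and NF-kB response, adipocytes, skeletal muscle, keratinocytes and hair follicle, erythroid cells, nerve and Schwann cells, and immediate early and heat shock. The lists, designs, alternatives and the rule for named genes were fixed before the data were examined.

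By that rule the text names, for each comparison, up to 8 of the largest rises and 8 of the largest falls among genes past the threshold with a mean log2 CPM of at least 1, whose compared groups did not overlap (the interaction excepted), leaving out predicted genes, pseudogenes, ribosomal, mitochondrial and antigen receptor segment genes. With 3 libraries against 3, chance leaves the groups of 10% of genes without overlap. It also names up to 4 members of each described list with the smallest p, and in each comparison could name Fap, Tnfrsf9, Tnfsf9, Cd8a, Ifng, Gzmb, Foxp3, Cd274, Cdkn1a and Mki67. Some genes that the rule selects are not reported here. A gene named outside the rule is said to have been chosen after its values were seen.

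The steps were tested on simulated counts drawn from the real means and library sizes with known changes. Of genes changed 2-fold, 57.8% were recovered for RT against control, with 4.07% of the calls false, over 17130 genes. For the interaction, 21.9% were recovered over 17139 genes.

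The alternatives were RLE factors or library totals in place of TMM, no low-count filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the 2 compared groups in a fit, each library left out in turn, and a stricter threshold for overlaps. A fit with the skeletal muscle score of each library as a covariate was added after seeing the data. Overlap between comparisons that share the control libraries was set against 20 simulations of unchanged groups. Real groupings were set against every other split of the 6 compared libraries, and for the interaction against 99 random regroupings of the 12 libraries.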

Results

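RNA was sequenced from mouse tumours grown from TS/A mammary carcinoma cells, a mouse breast cancer line, together with cancer-associated fibroblasts. The 12 libraries fell into 4 groups of 3: tumours with no active treatment (control), tumours given radiotherapy (RT), tumours given muFAP-4-1BBL (FAP41BBL), and tumours given both (RT_FAP41BBL). The agent muFAP-4-1BBL carries the ligand of the T cell costimulatory receptor 4-1BB and is directed to fibroblast activation protein, a surface protease of activated fibroblasts. Library totals lay between 35176469 and 38174041 counts in control, 39367317 and 42067481 in RT, 34076477 and 39069755 in FAP41BBL, and 37393177 and 38446771 in RT_FAP41BBL, and between 24171 and 25773 genes had at least 1 count in a library. No 2 libraries of a group were copies of one another, with a chi-square of at least 19.0 per degree of freedom between any such pair. The first and second principal components held 46.6% and 19.1% of the variance of the 2000 most variable genes. The first largely followed the skeletal muscle score of the libraries, also across groups. It ran from -51.7 in control replicate 3 (muscle score 1.66) to 65.5 in RT replicate 3 (9.1). In FAP41BBL replicates 2 and 3 it was -42.7 and 9.3 (2.24 and 6.37). The component is therefore not a measure of treatment alone. The labels do not tie the libraries to separate animals, so the p-values measure the spread between these samples, which may be technical. Levels are given in CPM, the counts of a gene scaled to a common library size, as mean ± SD over 3 libraries, and changes as log2 fold changes ± SE.

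The genes that encode the target, the receptor and its ligand were looked at first. Fap, which encodes fibroblast activation protein (ENSMUSG00000000392.18, chromosome 2, 62331287 to 62404419, GRCm39), stood at 7.83 ± 2.83 CPM in control, 14.1 ± 3.29 in RT, 10.8 ± 7.11 in FAP41BBL and 7.68 ± 2.37 in RT_FAP41BBL, and passed the test in none of the 6 comparisons. Tnfrsf9, which encodes 4-1BB (ENSMUSG00000028965.14, chromosome 4, 150999019 to 151030559), stood at 21.8 ± 2.15 CPM in control and at 31 ± 4.61, 32.9 ± 4.87 and 30.4 ± 4.44 in RT, FAP41BBL and RT_FAP41BBL, with adjusted p-values of 0.0506, 0.600 and 0.0691 against control. Tnfsf9, the gene of the mouse's own 4-1BB ligand, lay between 10.2 and 13.3 CPM and passed in no comparison. The same held for Foxp3, which marks regulatory T cells, for Ifng, the interferon-gamma gene, and for the proliferation marker Mki67.

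**Figure D1:**
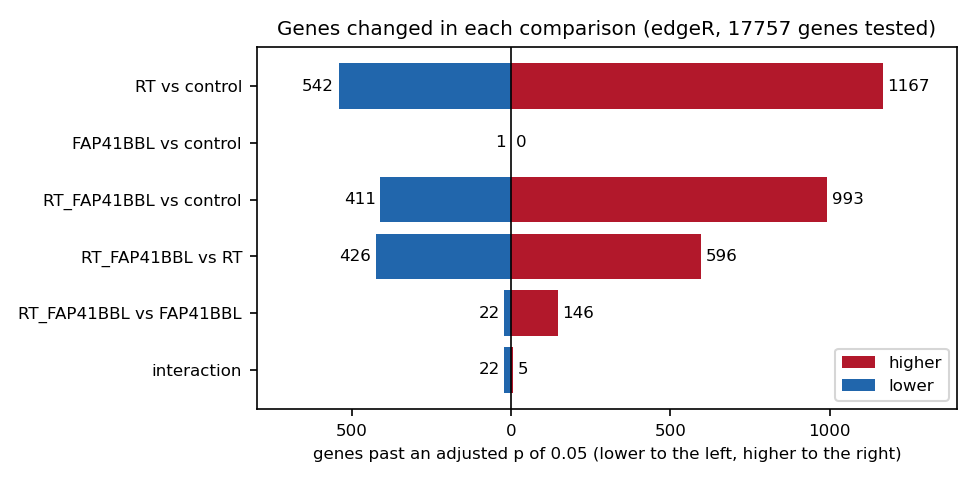
Genes past an adjusted p of 0.05 in each of the 5 pairwise comparisons and the interaction (horizontal axis, number of genes, lower to the left and higher to the right). RT against control gave 1167 higher and 542 lower genes, while FAP41BBL against control gave 1.

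RT against control addressed what radiotherapy alone changed. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases (ENSMUSG00000023067.15, chromosome 17, 29309950 to 29319701), rose from 41.9 ± 5.29 to 135 ± 19.6 CPM (log2 1.69 ± 0.14, adjusted p = 0.000144). Of 30 tested genes of the type I interferon list 29 rose, also adjusted over the list alone, with a median log2 change of 1.07. Genes of cytotoxic granules rose as well, among them Gzmb, from 21.3 ± 6.18 to 66.8 ± 11.5 CPM (log2 1.65 ± 0.33, adjusted p = 0.0112). Cx3cr1, a chemokine receptor of monocytes and macrophages, fell from 94.3 ± 18.6 to 24.8 ± 10.3 CPM (adjusted p = 0.00488). Transcripts of skeletal muscle were far higher in all 3 RT libraries than in any other library.

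In the type I interferon list the 4 members with the smallest p were Rsad2, an antiviral enzyme (log2 1.93), Usp18, a brake on interferon signalling (1.6), Oasl1, an antiviral sensor-related protein (1.51), and Cmpk2, a mitochondrial nucleotide kinase (1.40). The list had an adjusted p of 1.29e-27 by camera, and an adjusted p of 0.252 with an estimated correlation. The interferon-gamma response list had 6 of 29 members higher and 11 adjusted over the list alone, including Cxcl10, a T cell chemokine (1.10), and the GTPase genes Gbp3 (0.82), Irgm1 (0.80) and Tgtp1 (1.00). Its adjusted p was 0.000389, with an adjusted p of 0.622 with an estimated correlation. Of 30 p53 targets 9 rose and 1 fell, and 14 rose and 1 fell adjusted over the list alone. Beside Cdkn1a these were led by Ccng1, which encodes cyclin G1 (0.95), the nuclease gene Aen (0.75) and Sesn2, a stress-induced regulator of mTORC1 (0.81). The p53 list had an adjusted p of 3.01e-06, and 0.189 was the adjusted p with an estimated correlation.

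Of 25 cytotoxic effector genes 10 rose and 12 did so adjusted over the list alone, the largest among the leading members being the granzyme genes Gzmd (3.88), Gzme (3.55) and Gzmc (2.74), with Klrg1, a receptor of effector lymphocytes, at 1.5. This list had an adjusted p of 9.67e-06 and an adjusted p of 0.622 with an estimated correlation. The T cell list had no member past the test, with Cd8a, the CD8 alpha chain, at 16.6 ± 4.73 CPM in control and 8.62 ± 3.72 in RT (log2 -0.94 ± 0.32, adjusted p = 0.0933). Its median was -0.39 with an adjusted p of 0.0101, and an adjusted p of 0.622 with an estimated correlation. The T cell and monocyte chemokines had 7 of 18 members higher, 7 adjusted over the list alone, among them Ccl2 (1.67), Ccl7 (2.0) and Ccl3 (1.52), which draw monocytes. Their adjusted p was 0.00156, and an adjusted p of 0.622 resulted with an estimated correlation. The inflammatory list had 10 of 27 members higher and 15 adjusted over the list alone, led by the prostaglandin synthase gene Ptgs2 (1.80), Lcn2, an iron-binding acute phase protein (2.16), Tnf (1.82) and the cytokine gene Lif (0.70). Immediate early and heat shock genes had 9 of 23 members higher and 17 higher and 1 lower adjusted over the list alone, with the early response transcription factors Egr1 (1.66), Fosl1 (1.00) and Nr4a1 (0.88) and the heat shock gene Hsph1 (1.10). These 2 lists had adjusted p-values of 5.83e-07 and 1.55e-08, and an adjusted p of 0.252 each with an estimated correlation.

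MHC class II presentation had a median of -1.22 over 12 members. H2-Ob, a chain of the peptide-loading regulator H2-O, passed over all genes (log2 -1.77 ± 0.31, adjusted p = 0.00488), and 9 members were lower and 1 higher adjusted over the list alone. The list's adjusted p was 0.000357, and its adjusted p was 0.622 with an estimated correlation. The largest falls also held Mcpt1 (-4.91) and Mcpt2 (-3.01), mast cell proteases, the immunoglobulin constant gene Ighg2c (-3.94), Treml4, a receptor of myeloid cells (-2.09), Cd207, the Langerhans cell lectin langerin (-1.95), Tlr12, a toll-like receptor (-1.94), and Slc13a3, a dicarboxylate transporter (-1.84). Mcpt1 stood at 8.47 ± 12.5 CPM in control, so that one group spread widely. The mast cell and eosinophil list had a median of -0.90 with no member past the test (adjusted p = 0.0222, adjusted p = 0.622 with an estimated correlation). Among macrophage and monocyte genes 4 of 24 rose and 5 did so adjusted over the list alone, with Ly6c2, a monocyte surface protein, at 1.79, the Fc receptor gene Fcgr1 at 0.81 and Chil3, a chitinase-like secreted protein, at 3.45.

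The skeletal muscle list had a median of 4.32 over 21 members, with 12 higher over all genes and 21 adjusted over the list alone. The adjusted p was 1.89e-17, and the adjusted p was 0.354 with an estimated correlation. Actn3, the fast-fibre actinin, went from 7.36 ± 5.02 to 217 ± 106 CPM, with Mb, which encodes myoglobin, at 4.32 and the calcium release channel gene Ryr1 at 4.17. The largest rises of all were likewise genes of striated muscle: Myh7, the slow myosin heavy chain (10.65), Igfn1 (7.62), Myl2, a slow and cardiac myosin light chain (6.78), Ampd1, the AMP deaminase of muscle (4.99), Fsd2 (4.92), Ckmt2, the mitochondrial creatine kinase of muscle (4.87), and Tmem233 (4.79). With the muscle score as a covariate Ckmt2 and Tmem233 turned to -0.32 and -1.21, neither past the test. Ampd1, Fsd2, Actn3, Ryr1 and Mb shrank to 0.15, 0.56, 0.60, 0.39 and 0.86 under it, and none passed. The control levels of Myh7, Igfn1 and Myl2, 0.0374 ± 0.0648, 0.0632 ± 0.0574 and 0.102 ± 0.155 CPM, rest on very few reads, so their folds are imprecise. The 21 genes together held 0.786% to 1.81% of the counts in the RT libraries and 0.0258% to 0.286% in the other libraries. Across the 9 libraries outside the RT group, 623 genes followed the muscle score with a Spearman coefficient above 0.7, and 259 of the 1709 genes changed in RT against control were among them, all higher. They were 15.2% of the calls, against 3.51% of all genes. Muscle genes with very few reads outside RT cannot follow the score there, so 259 is not an upper bound.

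The other lists are given by their medians. Adipocyte genes had a median of 1.64 with 1 of 16 members higher (adjusted p = 0.00417, adjusted p = 0.622 with an estimated correlation). G2/M genes had -0.16 and G1/S genes 0.17 (adjusted p = 0.00663 each, adjusted p = 0.622 each with an estimated correlation), with the S phase genes Ccne1 (0.56) and Rrm2 (0.51) higher. Erythroid genes had -0.65 and keratinocyte and hair follicle genes -3.56, each with an adjusted p of 0.0393 and an adjusted p of 0.622 with an estimated correlation. Without control replicate 2 the keratinocyte median was 0.42 (adjusted p = 0.368). The remaining 13 lists missed the threshold: checkpoint and costimulation 0.19, regulatory T cells 0.30, B and plasma cells -0.23, MHC class I presentation 0.10, dendritic cells -0.20, macrophages and monocytes 0.22, neutrophils 0.22, fibroblasts 0.26, TGF-beta targets -0.04, endothelial cells 0.19, epithelial tumour cells -0.72, hypoxia and glycolysis -0.04, and nerve and Schwann cells 0.11. Single members of these lists passed, such as Tnfsf4, the OX40 ligand (1.77), Il10, an anti-inflammatory cytokine gene (0.92), Il11, a cytokine gene of the fibroblast response to TGF-beta (1.90), the collagen-binding proteoglycan gene Fmod (2.99), and Ddit4, an mTORC1 inhibitor (-1.15). Il10 (adjusted p = 0.049) lost its call in all 6 fits that left out a library, with adjusted p-values of 0.0627 to 0.185. TGF-beta targets had a mean of 0.26 and an upward test against a negative median, and nerve genes a downward test against a positive median and mean. The epithelial tumour cell list was low, with a score of 0.28 ± 1.42 in control against 7.24 ± 0.28 for fibroblasts. In control replicates 2 and 3 it scored 1.83 and -0.95, and the keratinocyte list 3.77 and -2.36. Changes of the epithelial list may therefore not follow the share of tumour cells in any comparison.

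In all, 1709 of 17757 genes passed by edgeR's quasi-likelihood test at an adjusted p under 0.05, 1167 higher and 542 lower. The count was 1053, 805 and 970 without control replicate 1, 2 and 3, and 1064 in a fit of the 2 groups alone. Of the 62 named genes 37 stayed past the test in every fit that left out a library, while Tmem233 lost its call in all 6, Ckmt2, Ighg2c, Ryr1 and Tgtp1 in 5, and Actn3, Ampd1, Irgm1, Mcpt1 and Rrm2 in 4. The gene count was 3 (Ptgs2, Ccl7 and Egr1) with the muscle score of each library as a covariate, a term that nearly coincides with the RT group. Under it 60 of the 62 named genes past the test kept their direction and 31 of these had larger changes, while their standard errors were a median of 1.67 times as large. Beside the muscle genes, Fmod shrank to 1.53 ± 0.67 (adjusted p = 0.424) and Chil3 to 1.92 ± 1.17 (adjusted p = 0.598). Cdkn1a went from 1.69 ± 0.14 to 1.55 ± 0.25 (adjusted p = 0.0726) and Rsad2 from 1.93 ± 0.24 to 2.38 ± 0.39 (adjusted p = 0.0835). Ptgs2 went from 1.80 ± 0.16 to 2.23 ± 0.24 (adjusted p = 0.0152). These errors widened, while the change of Cdkn1a was slightly smaller and that of Rsad2 larger. Fewer calls also make the adjusted threshold harder to reach, so wider errors alone need not account for the lost calls.

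FAP41BBL against control addressed what the targeted agonist did alone. Per1, a core clock gene that glucocorticoids also induce (ENSMUSG00000020893.18, chromosome 11, 68986043 to 69000786), fell from 124 ± 17.4 to 43.9 ± 7.35 CPM (log2 -1.5 ± 0.17, adjusted p = 0.0141) and was the single gene of 17757 past the threshold. Lists of T cells, cytotoxic effectors, checkpoint genes and inflammatory genes had positive medians, of 0.41, 0.61, 0.42 and 0.52, with nearly all of their members above 0. Cd8a stood at 17.8 ± 1.61 CPM against 16.6 ± 4.73 in control (adjusted p = 0.999), Gzmb at 34 ± 13.8 against 21.3 ± 6.18 (adjusted p = 0.991), and Cd274, which encodes the checkpoint ligand PD-L1, at 115 ± 29.7 against 72.2 ± 16.8 (adjusted p = 0.991).

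All 25 members of the cytotoxic list had a log2 change above 0, and 8 were higher adjusted over the list alone. The adjusted p was 1.38e-15, and the adjusted p was 0.187 with an estimated correlation. For the T cell list, 25 of 25 members lay above 0 and none passed adjusted over the list alone (adjusted p = 5.28e-09, adjusted p = 0.317 with an estimated correlation). Checkpoint and costimulation genes had 2 members higher adjusted over the list alone, and the inflammatory list had 10. Their adjusted p-values were 2.41e-09 and 2.15e-16, and the adjusted p-values were 0.187 and 0.109 with an estimated correlation. Immediate early and heat shock genes had a median of 0.46, with 8 members higher and 1 lower adjusted over the list alone (adjusted p = 8.64e-13, adjusted p = 0.187 with an estimated correlation). Adipocyte genes, such as the hormone gene Adipoq at 2.45 ± 1.88 CPM in control and 14.8 ± 8.47 in FAP41BBL, had a median of 2.57 and 12 of 16 members higher adjusted over the list alone (adjusted p = 8.12e-18, adjusted p = 0.187 with an estimated correlation). Adipoq was named after its values were seen. The type I interferon list had a median of 0.30 with no member past either adjustment (adjusted p = 2.97e-10, adjusted p = 0.329 with an estimated correlation).

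By camera with its preset correlation 21 of 29 lists passed, 17 up and 4 down, and with an estimated correlation none did, with 0.109 as the smallest adjusted p. Down by the preset test were erythroid (median -0.60, adjusted p = 4.41e-05), G2/M (-0.12, 0.000226), nerve and Schwann cell (-0.34, 0.0104) and mast cell and eosinophil genes (-0.36, 0.0459). Epithelial tumour cell (0.06, 0.000598) and endothelial genes (0.16, 0.0398) were among those up. Fibroblast genes (median -0.01, mean 0.04, test downward) and hypoxia genes (median -0.01, mean 0.03, test downward) differed in sign between measures, and MHC class II genes had a median of 0 with an upward test. By an unadjusted p under 0.05, 918 genes differed. Simulated changes of 2-fold were found for 57.8% of genes in this comparison, in a simulation that made 126 calls. More calls ease the adjusted threshold, so fewer would be found in a comparison with 1 call. Uncalled changes need not be modest: the adipocyte median was 2.57 with 0 of 16 members past the test over all genes. The fall of Per1 lost its call without control replicate 1 (adjusted p = 0.109) and without control replicate 2, where 0 genes passed, while 3 genes passed without control replicate 3, and 2 without FAP41BBL replicate 1 or 3. The gene count was 48 with DESeq2, 9 with no low-count filter, 2 with the muscle covariate, 0 with the 2 groups alone, and 1 each with limma-voom, RLE factors and library totals.

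**Figure D2:**
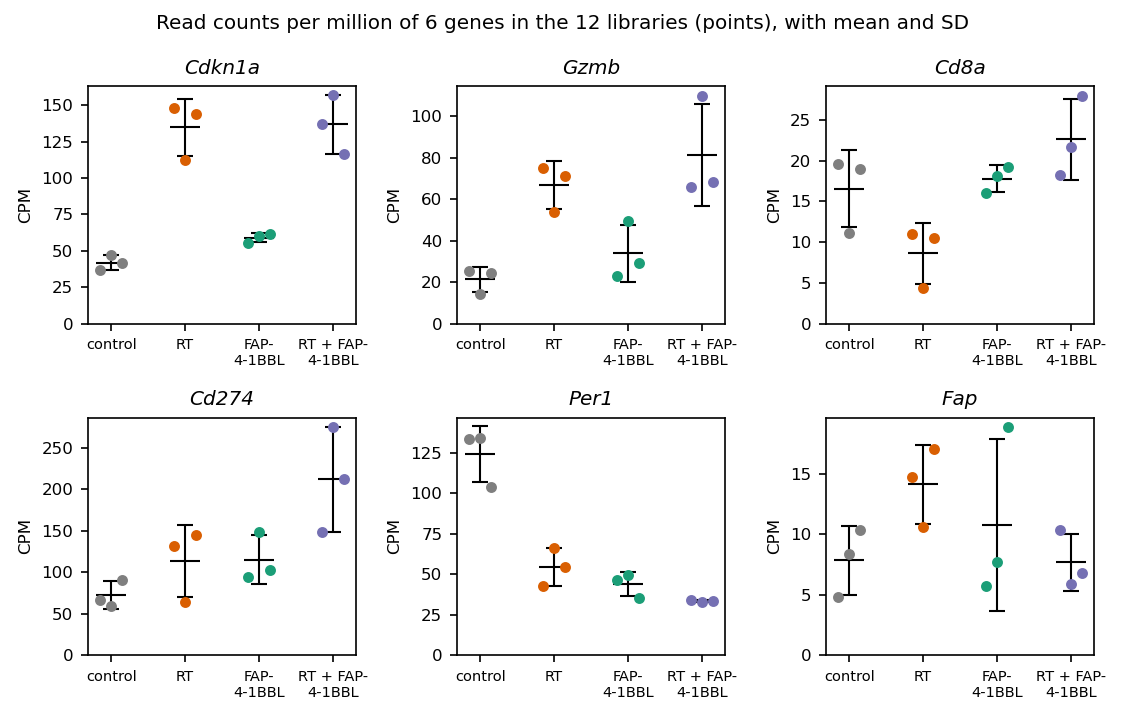
CPM of Cdkn1a, Gzmb, Cd8a, Cd274, Per1 and Fap (vertical axes) in each library of the 4 groups, with points for libraries and bars for mean and SD. Cdkn1a was above 110 CPM only in the irradiated groups, and Per1 was highest in control at 124 ± 17.4 CPM.

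RT_FAP41BBL against control addressed the combined treatment. Tnf, an inflammatory cytokine gene, rose from 3.44 ± 1.09 to 23.4 ± 6.58 CPM (log2 2.76 ± 0.36, adjusted p = 0.00246), Cdkn1a from 41.9 ± 5.29 to 137 ± 20.4 CPM (1.71 ± 0.14, adjusted p = 0.000251) and Gzmb from 21.3 ± 6.18 to 81.4 ± 24.7 CPM (1.94 ± 0.33, adjusted p = 0.00758). Cd274 rose from 72.2 ± 16.8 to 212 ± 63.5 CPM (1.56 ± 0.33, adjusted p = 0.0197). Interferon-stimulated, cytotoxic, chemokine and macrophage genes rose in number, and enzymes that make sterols were among the largest falls. Per1 fell to 33.5 ± 0.751 CPM (-1.89 ± 0.17, adjusted p = 0.000406).

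The type I interferon list again had 29 of 30 members higher and 30 adjusted over the list alone, with a median of 1.19. Irf7, the transcription factor that amplifies interferon production, rose by 1.81, Oasl1 by 1.62, Ifi27l2a by 1.13 and Rtp4 by 1.07. The list had an adjusted p of 4.32e-30, and an adjusted p of 0.164 with an estimated correlation. Of the interferon-gamma response genes 12 of 29 rose, 25 adjusted over the list alone, with a median of 0.85 (adjusted p = 2.69e-13, adjusted p = 0.344 with an estimated correlation). Cytotoxic effectors had 12 of 25 members higher, 22 adjusted over the list alone, and a median of 1.20, with Prf1, the pore-forming protein perforin, at 1.67, Gzmc at 1.95 and Ccl5, a chemokine made by T cells, at 1.96. Checkpoint and costimulation genes had 7 of 19 higher, 16 adjusted over the list alone, and a median of 0.79, with the inhibitory receptor genes Havcr2 (1.08) and Tigit (0.59), the costimulator Icos (0.98) and Tnfsf4 (2.03). These lists had adjusted p-values of 6.65e-15 and 2.06e-10, and the adjusted p-values were 0.178 and 0.164 with an estimated correlation. In the T cell list Cd2 (0.92), Cd4 (0.91) and Cd28 (1.04) rose, and 5 members were higher and 1 lower adjusted over the list alone, while Cd8a stood at 22.6 ± 4.96 CPM (0.45 ± 0.32, adjusted p = 0.435). Of the 6 fits that left out a library, Cd28 lost its call in 6, Cd4 in 5 and Cd2 in 4, with adjusted p-values of up to 0.182, 0.128 and 0.133, each without control replicate 2. The T cell median was 0.56 (adjusted p = 5.94e-06, adjusted p = 0.442 with an estimated correlation).

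Of 30 p53 targets 13 rose, 17 adjusted over the list alone, including Sesn2 (0.83) and the antiproliferative gene Btg2 (0.95), with a median of 0.42 (adjusted p = 2.38e-08, adjusted p = 0.0776 with an estimated correlation). Macrophage and monocyte genes had 9 of 24 higher and 12 adjusted over the list alone, with Ly6c2 (1.69), Fcgr1 (1.30), Ms4a7 (1.42) and Adgre1, which encodes F4/80 (1.33). Chemokines had 9 of 18 higher and 10 adjusted over the list alone, with Ccl3 at 2.22, Ccl7 at 1.62 and Ccl2 at 1.40. The 2 lists had adjusted p-values of 4.43e-07 and 8.40e-07, and the adjusted p-values were 0.209 and 0.235 with an estimated correlation. Inflammatory genes had 9 of 27 higher and 14 adjusted over the list alone, with Ptgs2 at 1.40, the NF-kB regulator Nfkbiz at 1.16 and the adhesion molecule Icam1 at 1.15 (adjusted p = 8.07e-08, adjusted p = 0.164 with an estimated correlation). In the regulatory T cell list Il1rl1 (0.79), Ebi3 (1.19), Il10 (1.64) and Il2ra (0.90) rose, genes of cytokines and cytokine receptors that other immune cells also use, and 5 members were higher adjusted over the list alone (adjusted p = 2.25e-05, adjusted p = 0.164 with an estimated correlation). Adipocyte genes had a median of 2.85, with 3 of 16 higher and 16 adjusted over the list alone (adjusted p = 1.64e-07, adjusted p = 0.393 with an estimated correlation). G2/M genes had a median of -0.30 with no member past the test (adjusted p = 2.01e-06, adjusted p = 0.475 with an estimated correlation). The skeletal muscle median was 0.96 with no member past either adjustment (adjusted p = 0.00349, adjusted p = 0.625 with an estimated correlation).

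The largest rises beyond those named were Prlr, the prolactin receptor (4.99), Cyp2e1, a cytochrome P450 (4.61), the serine protease gene Htra4 (3.05), Gzmf (2.86), Fcrl5, an Fc receptor-like protein of B cells (2.68), Gzmd (2.63) and Ifit1bl1, an interferon-induced gene (2.54). In the 3 RT_FAP41BBL libraries Prlr stood at 8.59, 0.402 and 18.7 CPM and Cyp2e1 at 38.9, 4.34 and 37.0 CPM, against at most 0.360 and 1.73 in control. The second of these libraries also had the lowest adipocyte score of the group, 2.63 against 4.39 and 4.57. Both calls were lost in 5 of the 6 fits that left out a library, with adjusted p-values of up to 0.124 and 0.135. In FAP41BBL, without a call, Prlr stood at 3.10, 8.56 and 14.2 CPM and Cyp2e1 at 10.3, 17.2 and 30.5 CPM. High levels of these genes were therefore not particular to the combined treatment. The largest falls were Idi1 (-2.36), Fdps (-1.96) and Cyp51 (-1.91), which encode enzymes of isoprenoid and cholesterol synthesis, with Csdc2 (-2.09), Lrrc75b (-1.82) and Jchain, the joining chain of secreted antibodies (-1.73).

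Of 17757 genes 1404 passed, 993 higher and 411 lower, and 18 of 29 lists passed camera, 16 up and 2 down, while none did with an estimated correlation, where the smallest adjusted p was 0.0776. Fibroblast genes (median -0.03, mean 0.03, test downward) and epithelial tumour cell genes (median -0.07, mean 0.37, test upward) differed in sign between measures. The gene count was 790, 351 and 703 without control replicate 1, 2 and 3, 914, 442 and 582 without RT_FAP41BBL replicate 1, 2 and 3, 811 with the muscle covariate, 2325 with DESeq2, and 3223 with the 2 groups alone. The call of Cd274 was lost without control replicate 2, with an adjusted p of 0.0934, and in 3 more fits that left out a library. Of the 50 named genes 32 stayed past the test in every such fit, while Csdc2 lost its call in all 6, Fdps, Gzmf and Jchain in 5 and Il2ra in 4. With the muscle covariate all 50 kept their direction and 43 their call. The calls lost under it were those of Cd2, Cd28, Il2ra, Prlr, Cyp2e1, Csdc2 and Jchain, with adjusted p-values of 0.0555 to 0.117.

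Calls against control were compared between the treated groups. RT and RT_FAP41BBL shared 512 genes changed in one direction, 318 higher and 194 lower, and 1 gene changed in opposite directions. Lists drawn independently would share 65.3 higher and 12.5 lower genes. In 20 simulations with no effect in either group 0 genes were shared, but these simulations made 0.15 calls per comparison on average, so that value does not measure the overlap of real calls. Across genes the fold changes had a Pearson r of 0.566, against 0.498 simulated from the shared controls alone, and a covariance of 0.276 against 0.0642. Between FAP41BBL and RT_FAP41BBL r was 0.727 (simulated 0.496) and the covariance 0.211 (simulated 0.0643), and between FAP41BBL and RT r was 0.541 (simulated 0.497) and the covariance 0.209 (simulated 0.0643). Per1 was the 1 gene that FAP41BBL shared with either group, and it fell from 124 ± 17.4 CPM in control to 54.5 ± 11.7 CPM in RT (adjusted p = 0.00165). With 3 controls the controls could not be split into parts of 2 libraries each, so part of the excess may come from the shared control libraries.

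RT_FAP41BBL against RT addressed what the agonist added to radiotherapy. The T cell coreceptor genes rose, with Cd4 at 21.2 ± 4.16 CPM against 7.83 ± 1.71 (log2 1.44 ± 0.23, adjusted p = 0.00844) and Cd8a at 22.6 ± 4.96 against 8.62 ± 3.72 (1.39 ± 0.32, adjusted p = 0.0321). MHC class II genes had a median of 1.51, and muscle genes a median of -3.43. Against control the MHC class II median was -1.22 in RT and 0.36 in RT_FAP41BBL (adjusted p = 0.053 by camera with its preset correlation). The MHC class II difference thus lay mostly in low values in RT. Part of the T cell difference did as well, with a T cell median against control of -0.39 in RT and 0.56 in RT_FAP41BBL. Cd8a stood between 11.12 and 19.65 CPM in the control libraries. Gzmb stood at 81.4 ± 24.7 CPM against 66.8 ± 11.5 (adjusted p = 0.642) and Cdkn1a at 137 ± 20.4 against 135 ± 19.6 (adjusted p = 0.947). Cxcl13, the chemokine that attracts B cells, rose from 18.6 ± 12.4 to 82.4 ± 16.5 CPM (2.15 ± 0.43, adjusted p = 0.0232).

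Of 25 T cell genes 9 rose and 21 did so adjusted over the list alone, with a median of 0.95. Among them were Cd6, a T cell surface receptor (1.28), and Trac, the T cell receptor alpha constant gene (1.03). The list had an adjusted p of 5.91e-11, and an adjusted p of 0.457 with an estimated correlation. Checkpoint and costimulation genes had 5 of 19 higher and 14 adjusted over the list alone, including Havcr2 (0.89), Lag3 (0.96) and Tox, a transcription factor of exhausted T cells (1.39). Of the 12 MHC class II genes 5 rose and all 12 were higher adjusted over the list alone, with H2-Ob at 1.42, H2-DMb2 at 1.63 and the lysosomal proteases Ctss (0.95) and Lgmn (0.52). These lists had adjusted p-values of 1.25e-07 and 3.43e-09, and an adjusted p of 0.457 each with an estimated correlation. Macrophage and monocyte genes had 8 of 24 higher and 12 adjusted over the list alone, with the complement genes C1qa (0.91) and C1qb (0.96) and Adgre1 (0.83) (adjusted p = 0.00116, adjusted p = 0.566 with an estimated correlation). Dendritic cell genes had 3 higher and 1 lower, with Xcr1 (1.80) and Batf3 (1.27), markers of cross-presenting dendritic cells, and Itgax, which encodes CD11c (1.81), higher and the melanosome transport gene Mreg lower (-1.19). Adjusted over the list alone 7 were higher and 1 lower (adjusted p = 0.0474, adjusted p = 0.620 with an estimated correlation). The B cell genes Cd79b (1.76) and Cd22 (1.01) rose, with 4 of 16 members higher adjusted over the list alone (adjusted p = 0.0187, adjusted p = 0.620 with an estimated correlation). Type I interferon genes had a median of 0.10 with no member past either adjustment (adjusted p = 0.664). Without RT_FAP41BBL replicate 2 that median was -0.15 (adjusted p = 0.00895 by camera with its preset correlation), without RT_FAP41BBL replicate 3 it was 0.25 (adjusted p = 0.00447), and with the muscle covariate it was -0.14 (adjusted p = 0.022). Mast cell and eosinophil genes had a median of 1.02, with all 14 members above 0 and 3 higher adjusted over the list alone (adjusted p = 0.000465, adjusted p = 0.566 with an estimated correlation). The medians were 1.00 for epithelial tumour cells with 1 of 22 members higher, 0.93 for adipocytes with 1 of 16 higher and 0.22 for endothelial cells with 2 of 21 higher adjusted over the list alone. Their adjusted p-values were 0.0314, 0.0132 and 0.0477, with an adjusted p of 0.706 each with an estimated correlation. The epithelial list was low in both groups, with scores of -0.25 ± 0.55 in RT and 0.96 ± 1.1 in RT_FAP41BBL, and may not follow tumour cells. Interferon-gamma response, MHC class I and cytotoxic genes had medians of 0.35, 0.18 and 0.41 (adjusted p = 0.000108, 0.0113 and 0.0188, adjusted p = 0.706 each with an estimated correlation). Regulatory T cell genes had 0.67 (adjusted p = 0.0058, adjusted p = 0.457 with an estimated correlation).

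In the skeletal muscle list Eno3, the muscle enolase, fell (-1.26), and 21 of 21 members were lower adjusted over the list alone (adjusted p = 7.79e-15, adjusted p = 0.457 with an estimated correlation). The muscle genes held 0.0845% to 0.142% of the counts in the RT_FAP41BBL libraries against 0.786% to 1.81% in RT. Myh7 (-7.55), Myl2 (-6.22), Igfn1 (-6.00), Ampd1 (-4.51), Thbs4, a thrombospondin of tendon and muscle (-4.34), Phkg1, a muscle phosphorylase kinase subunit (-4.11), Angptl1 (-3.89) and Scn4b, a sodium channel subunit (-3.79), were the largest falls. Of these, Myh7, Myl2 and Igfn1 stood at only 0.338 ± 0.497, 0.149 ± 0.0371 and 0.201 ± 0.0615 CPM in RT_FAP41BBL, so their folds are imprecise too. The largest rises were Klra17 (2.64), Lilra5 (2.28) and Sh2d1b1 (2.05), genes of leukocyte receptors and their adaptors, Slc13a3 (2.26), Fcrl5 (2.06) and Tlr12 (2.03). Slc13a3 and Tlr12 had been among the largest falls in RT against control (-1.84 and -1.94). Hsph1 (-1.25) and Hsp90aa1 (-0.57), heat shock proteins, and Ccng1 (-0.56) also fell, and the immediate early and heat shock list had a median of -0.14 (adjusted p = 0.0314, adjusted p = 0.706 with an estimated correlation), which was 0.002 without RT replicate 1.

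Of 17757 genes 1022 passed, 596 higher and 426 lower, and 16 of 29 lists passed camera, 14 up and 2 down, while none did with an estimated correlation, where the smallest adjusted p was 0.457. Neutrophil genes (median -0.02, mean 0.47, test upward) and inflammatory genes (median -0.03, mean -0.02, test upward) differed in sign between measures. The gene count was 462, 205 and 70 without RT_FAP41BBL replicate 1, 2 and 3, 448, 303 and 2305 without RT replicate 1, 2 and 3, 2063 with DESeq2 and 3 with the muscle covariate, and the list count was 10 without RT replicate 2. Under the covariate the 39 named genes past the test all kept their direction and none its call, 11 had larger changes, and their standard errors were a median of 1.42 times as large. Cd4 went from 1.44 ± 0.23 to 1.18 ± 0.30 (adjusted p = 0.158), Cd8a from 1.39 ± 0.32 to 1.33 ± 0.46 (adjusted p = 0.238) and Cxcl13 from 2.15 ± 0.43 to 2.29 ± 0.60 (adjusted p = 0.179), while the muscle gene Ampd1 went from -4.51 ± 1.10 to -0.76 ± 0.28 (adjusted p = 0.256). The share of higher genes was 36.3% in a fit of the 2 groups alone against 58.3%, and the call of Cd8a was lost in 5 of the 6 fits that left out a library, with an adjusted p of up to 0.135. Of the 39 named genes 10 stayed past the test in every such fit. Ampd1 lost its call in all 6, Adgre1, Cd22, Fcrl5, Hsp90aa1, Itgax, Klra17, Lag3, Lgmn and Scn4b in 5, and C1qa, Ctss, Cxcl13, H2-Ob, Mreg and Xcr1 in 4.

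**Figure D3:**
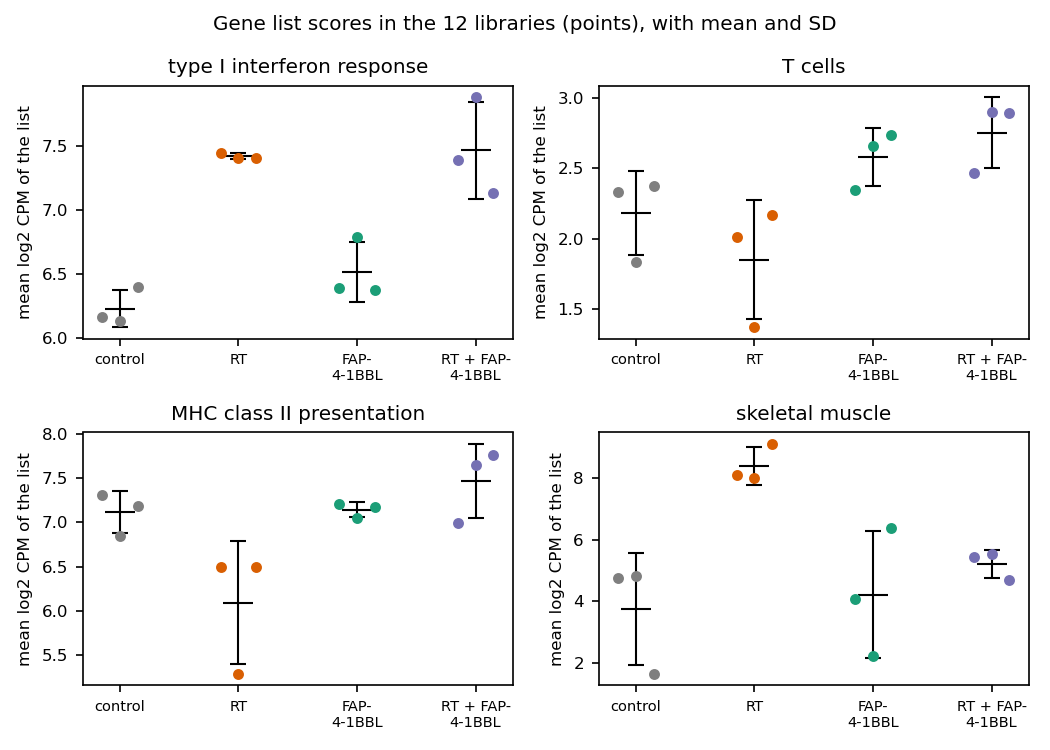
Mean log2 CPM of the type I interferon, T cell, MHC class II and skeletal muscle lists (vertical axes) in each library of the 4 groups, with points for libraries and bars for mean and SD. The muscle score was between 7.99 and 9.10 in RT and at most 6.37 elsewhere, and the MHC class II score was 5.29 to 6.49 in RT and at least 6.85 elsewhere.

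RT_FAP41BBL against FAP41BBL addressed what radiotherapy added to the agonist. Type I interferon genes were higher, with 16 of 30 past the test and 30 adjusted over the list alone, and a median of 0.93. Irf7 rose from 342 ± 52.6 to 970 ± 322 CPM (log2 1.5 ± 0.20, adjusted p = 0.0188) and Cdkn1a from 59.0 ± 3.12 to 137 ± 20.4 CPM (1.21 ± 0.14, adjusted p = 0.0188). Mgl2, a lectin of macrophages and dendritic cells, fell from 14.3 ± 3.41 to 2.73 ± 1.20 CPM (-2.38 ± 0.35, adjusted p = 0.0188). Gzmb stood at 81.4 ± 24.7 against 34 ± 13.8 CPM (adjusted p = 0.0963).

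The type I interferon list had an adjusted p of 3.85e-33, and an adjusted p of 0.180 with an estimated correlation. Beside Irf7 it was led by Ifit3b (1.67), Oasl1 (1.22) and Ifi27l2a (0.81). Of 30 p53 targets 4 rose and 12 did so adjusted over the list alone, with Dcxr, a carbonyl reductase (1.02), Sesn2 (0.73) and Aen (0.49) beside Cdkn1a (adjusted p = 4.23e-07, adjusted p = 0.118 with an estimated correlation). Macrophage and monocyte genes had 4 of 24 higher, namely Ly6c2 (1.30), Ms4a7 (1.18), Adgre1 (1.10) and Fcgr1 (0.99), and 12 higher and 2 lower adjusted over the list alone (adjusted p = 8.67e-07, adjusted p = 0.453 with an estimated correlation). Ccl5 (1.67), Havcr2 (1.01), Il10 (1.28) and the MHC class I gene H2-T24 (1.19) rose. The T cell list had a median of 0.23 with no member past either adjustment (adjusted p = 0.137). Skeletal muscle genes had a median of 0.01 with no member past either adjustment (adjusted p = 0.0116, adjusted p = 0.854 with an estimated correlation). That median was -0.007 with library totals and between -0.39 and -0.112 without FAP41BBL replicate 1 or 2 or RT_FAP41BBL replicate 1 or 2, but 1.84 without FAP41BBL replicate 3, the library with the highest muscle score outside RT (6.37).

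The largest rises also held Fcrl5 (2.69), Htra4 (2.21), Cd300e, a receptor of monocytes (2.09), Ifit1bl1 (1.80), Slfn4, a myeloid schlafen gene (1.77), and Tex14 (1.71). The largest falls held Cyp51 (-1.70), Sqle (-1.41), Hmgcs1 (-1.16) and Fdft1 (-1.07), which encode enzymes of cholesterol synthesis, Insig1 (-1.02) and Srebf2 (-0.97), which encode a sensor and the transcription factor that control it, and Gpr34, a receptor of macrophages and microglia (-1.03).

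In all 168 genes passed, 146 higher and 22 lower, and 14 of 29 lists passed camera, 12 up and 2 down, while none did with an estimated correlation, where the smallest adjusted p was 0.118. The gene count was 0, 132 and 4 without FAP41BBL replicate 1, 2 and 3, 22, 3 and 77 without RT_FAP41BBL replicate 1, 2 and 3, 783 with DESeq2, 269 with the 2 groups alone and 110 with the muscle covariate. At an unadjusted p under 0.05, 2398 genes differed. Of the 30 named genes 0 stayed past the test by edgeR in every fit that left out a library, and Adgre1, Aen, Dcxr and Gpr34 lost their calls in all 6. The sign differed between median, mean and test for 7 lists whose medians were 0.03 for fibroblasts, 0.05 for TGF-beta targets, 0.07 for epithelial tumour cells, 0.13 for adipocytes, -0.50 for keratinocytes, 0.11 for nerve genes and 0.14 for immediate early genes.

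**Figure D4:**
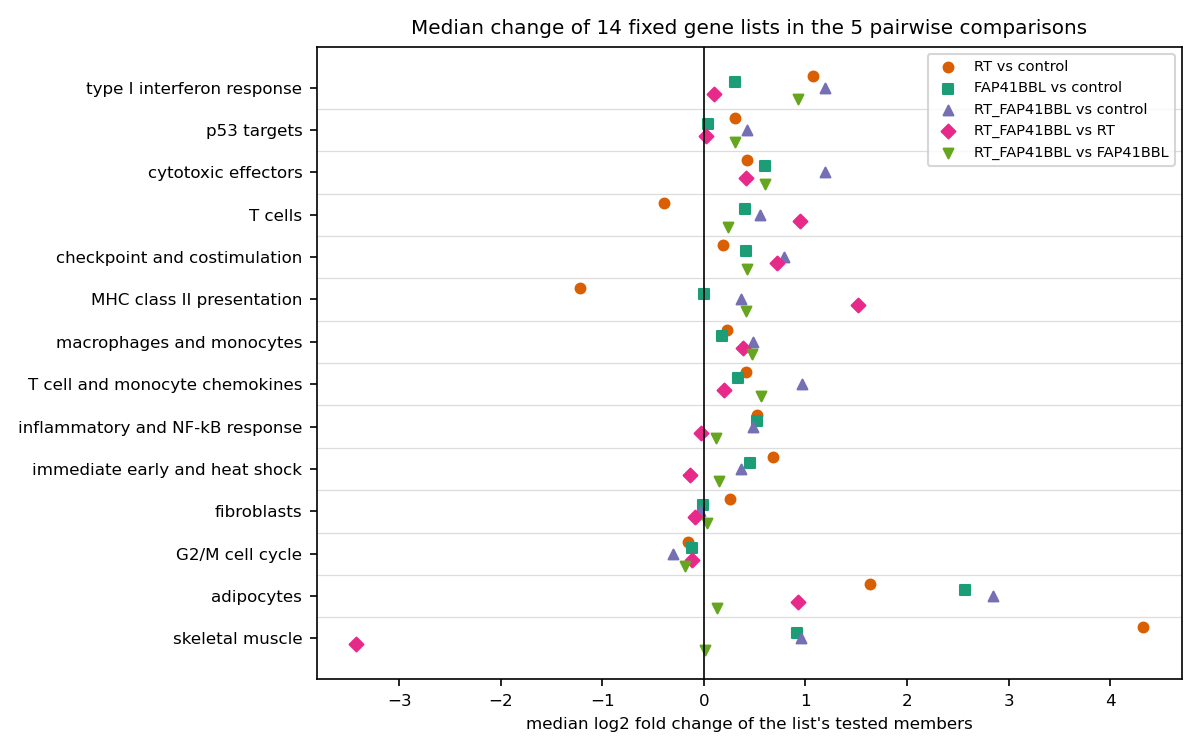
Median log2 fold change of 14 fixed gene lists (horizontal axis) in the 5 pairwise comparisons (symbols). The type I interferon median was 1.07 and 1.19 for RT and RT_FAP41BBL against control, and the skeletal muscle median was 4.32 for RT against control and -3.43 for RT_FAP41BBL against RT.

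The interaction of RT and FAP41BBL addressed whether the effect of radiotherapy differed with the agonist present. Of 17757 genes 27 passed, 5 higher and 22 lower. Without RT replicate 3 this balance turned, with 269 genes past the test, 177 higher and 92 lower. Sla, an adaptor that dampens T cell receptor signalling, stood at 87.1 ± 1.94 CPM in control, 38.0 ± 7.67 in RT, 53.5 ± 12.5 in FAP41BBL and 88.8 ± 1.76 in RT_FAP41BBL (interaction 1.92 ± 0.23, adjusted p = 0.0154). Clu, the secreted chaperone clusterin, stood at 18.7 ± 5.69, 66 ± 13.1, 21.5 ± 2.54 and 20.6 ± 2.25 CPM in the same order (-1.89 ± 0.29, adjusted p = 0.0311). The largest falls among the named genes were those of the muscle genes Igfn1 (-6.65) and Mss51 (-3.22), and the skeletal muscle list had a median of -4.26 with 19 of 21 members lower adjusted over the list alone (adjusted p = 1.14e-13, adjusted p = 0.636 with an estimated correlation). Outside RT Igfn1 stood at means of 0.0632 to 0.201 CPM, which rest on very few reads, so its interaction is imprecise. Of the 22 lower genes 3 followed the muscle score across the 9 libraries outside the RT group with a Spearman coefficient above 0.7. They were 11.1% of the 27 calls, against 3.51% of all genes. Genes that are low and even outside RT cannot follow the score there, so the count does not bound the share of muscle genes. Mss51, for one, stood at 13.4 to 21.3 CPM in RT and 1.4 to 2.39 CPM elsewhere. Ptgs2 had an interaction of -1.48, Hsph1 of -1.70 and Plk2, a p53-induced kinase, of -0.70. Cd8a (1.29, adjusted p = 0.230), Gzmb (-0.39, adjusted p = 0.761), Cd274 (0.23, adjusted p = 0.877) and Cdkn1a (-0.47, adjusted p = 0.297) did not pass.

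By camera 10 of 29 lists passed, 5 up and 5 down, and none did with an estimated correlation, where every list had an adjusted p of at least 0.636. Between median, mean and test the sign differed for dendritic cell (median -0.01), endothelial (0.01), G2/M (0.02) and chemokine (-0.25) genes. The gene count was 14, 17 and 269 without RT replicate 1, 2 and 3, 6, 104 and 8 without FAP41BBL replicate 1, 2 and 3, 8, 1 and 8 without control replicate 1, 2 and 3, and 0 by edgeR without RT_FAP41BBL replicate 1, 2 or 3, where 2497 genes had an unadjusted p under 0.05 with all libraries. It was 639 with DESeq2, 102 with no low-count filter, 17 with library totals and 0 with the muscle covariate, and in simulation 21.9% of 2-fold interactions were found. Under the covariate all 16 named genes kept their direction, 4 had larger changes, and their standard errors were a median of 1.21 times as large. Hsph1 went from -1.70 ± 0.23 to -1.71 ± 0.29 (adjusted p = 0.172) and Sla from 1.92 ± 0.23 to 1.71 ± 0.28 (adjusted p = 0.157). Others shrank more: Tspan8 from -3.13 ± 0.48 to -1.96 ± 0.41, Pkia from -2.58 ± 0.41 to -1.68 ± 0.32 and Hspb6 from -1.81 ± 0.28 to -1.15 ± 0.22. Of these 16 genes 0 stayed past the test by edgeR in every one of the 12 fits that left out a library.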

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

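The tests of muscle and MHC class II explanations in this part were chosen after the results were seen, as was the look at which libraries a regrouping set apart, while the counts over regrouped libraries were planned. The results below stood out by the interaction term of the model, in which the change with radiotherapy differed with the agonist present. For each lower gene named below, the lowest RT library lay above every library of the other groups. Muscle tissue in the RT samples only would give such a term for muscle genes without a different effect of radiotherapy. With the muscle score as a covariate, which nearly coincides with the RT group, 0 genes passed by edgeR. The interaction had 27 genes past the threshold and 10 lists past camera. Cyp26b1, which degrades retinoic acid, had an interaction of 2.95, Slc13a3 of 2.56, Sla of 1.92, Abhd15 of 1.76 and Jaml, a leukocyte adhesion molecule, of 1.27. Igfn1 had -6.65, a value that rests on very few reads outside RT, Mss51 -3.22, Tspan8 -3.13, Camk2a -2.66, Pkia -2.58, Clu -1.89, the small heat shock protein gene Hspb6 -1.81 and Ankrd23 -1.79. The list medians were 0.55 for T cells, -0.22 for type I interferon response, 0.20 for MHC class I presentation, 1.54 for MHC class II presentation, 1.46 for mast cells and eosinophils, -0.36 for the inflammatory and NF-kB response, -1.30 for adipocytes, -4.26 for skeletal muscle, 1.00 for erythroid cells and -0.60 for immediate early and heat shock genes. All 10 missed the threshold with an estimated correlation, where the smallest adjusted p was 0.636.

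Of 100 groupings of the 12 libraries, the real one included, 3 gave at least 27 interaction genes. The highest other gave 526 genes, several times the real count, which points to a structure of the samples: it set the 6 irradiated libraries against the 6 others, so its contrast held the effect of radiotherapy. The third that reached the count, with 445 genes, had 5 of the 6 irradiated libraries on one side. Of 52 other groupings balanced for irradiation 0 reached the count, with 2 genes as the highest by edgeR, and of 40 that were 1 library off balance 0 did, with 21 as the highest. The 99 other groupings had a common biological coefficient of variation of 0.242 to 0.318 against 0.205, because treatment effects entered the spread within their groups, and a wider spread leaves fewer calls. The share of 3 in 100 therefore does not settle whether chance can be excluded for the gene count. That count was 1 without control replicate 2 and 0 by edgeR without RT_FAP41BBL replicate 1, 2 or 3, where 2497 genes had an unadjusted p under 0.05 and 639 passed with DESeq2 with all libraries. For the lists, 78 of 100 groupings gave at least 10, with 22 as the highest other, so chance cannot be excluded for the list count.

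Skeletal muscle transcripts were high in the RT libraries, with a median of 4.32 against control. For all 21 fixed muscle genes the lowest RT library lay above the highest library of the other groups, which restates the pattern and decides nothing about its source. A lower share of tumour cells was predicted to raise muscle and erythroid genes alike. The lowest RT library exceeded the highest control library in muscle minus erythroid score by 4.09, against a summed SD of 1.67, so they did not rise alike. Muscle tissue in a sample would itself lower the share of tumour cells without raising erythroid genes, so the gap does not exclude a lower share. Radiotherapy raising muscle genes alike in both irradiated groups is argued against by a gap of 2.46 between the lowest RT and the highest RT_FAP41BBL library, with a larger SD of 0.61. Muscle tissue in the RT samples, from sampling or tumour site, and a response of muscle limited to RT stay open, since the labels do not describe dissection.

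MHC class II transcripts were lower in RT than in RT_FAP41BBL. Dilution by muscle RNA would lower interferon genes by the same amount, if muscle held few interferon transcripts and both groups had like interferon induction. That assumption was not tested. The lowest RT library exceeded the highest RT_FAP41BBL library in interferon minus MHC class II score by 0.52, so under it the scores did not fall alike. RT replicate 2 had the lowest score, and without it the median difference was 1.22. With the muscle score as a covariate the median was 1.6. The muscle scores of RT (7.99 to 9.1) and RT_FAP41BBL (4.7 to 5.53) did not overlap, so that fit cannot exclude a trend with muscle. An effect of the agonist in irradiated tumours stays open, no biological explanation was tested, and the list missed the threshold with an estimated correlation (adjusted p = 0.457).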

How the results depend on the processing

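Most values kept their direction under the alternatives, while counts of calls moved widely, and except where a reason is given the cause was not tested. The muscle covariate was chosen after seeing the data. It nearly coincides with the RT group, so it raises standard errors there, and the muscle list was not retested under its own score. Changes of 1.5-fold were recovered for 23.1% of simulated genes in RT against control, which limits what these depths and 3 libraries per group can show. With DESeq2 the counts were 48 for FAP41BBL and 2325 for RT_FAP41BBL against control, 2063 for RT_FAP41BBL against RT, 783 against FAP41BBL and 639 for the interaction. With only the 2 compared groups they were 1064 for RT, 0 for FAP41BBL (edgeR, 918 at an unadjusted p under 0.05 with all groups, 48 with DESeq2 and 1 with limma-voom) and 3223 for RT_FAP41BBL against control, and 269 for RT_FAP41BBL against FAP41BBL. With no low-count filter they were 9 for FAP41BBL and 102 for the interaction, and with library totals 17 for the interaction. With the muscle covariate they were 3 for RT, 2 for FAP41BBL and 811 for RT_FAP41BBL against control, 3 against RT, 110 against FAP41BBL and 0 for the interaction. At an adjusted p of 0.01, RT and RT_FAP41BBL shared 123 genes.

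With the replicate number as a block the interaction had 9 genes, 8 of them among the 27. The number did not pair the samples: of 18 same-numbered pairs 6 correlated above 0.1, from -0.344 to 0.432, among them all 3 pairs of RT with FAP41BBL (0.309, 0.176 and 0.432), and 6 of 12 libraries were closest to their own number. The block gave 1702, 1, 1564, 1172 and 163 genes in the 5 pairwise comparisons.

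Of the lists, 0 passed in each of the 6 comparisons with an estimated correlation. By fry 5 passed for RT, 0 for FAP41BBL and 11 for RT_FAP41BBL against control, 5 for RT_FAP41BBL against RT, 2 against FAP41BBL and 0 for the interaction. For RT these were, with adjusted p-values by fry, p53 targets (0.000614), type I interferon (0.00364), inflammatory and immediate early (0.00631 each) and skeletal muscle genes (0.0162). For RT_FAP41BBL against control they included p53 targets (0.000151) and type I interferon genes (0.00222). Leaving out each library in turn gave 805 to 1987 genes for RT, 0 to 3 for FAP41BBL and 351 to 914 for RT_FAP41BBL against control, 70 to 2305 against RT, 0 to 132 against FAP41BBL and 0 to 269 for the interaction, and 10 to 16 lists for RT_FAP41BBL against RT. Of the named genes past the threshold, 37 of 62 stayed past it in every such fit for RT, 0 of 1 for FAP41BBL and 32 of 50 for RT_FAP41BBL against control, 10 of 39 against RT, 0 of 30 against FAP41BBL and 0 of 16 for the interaction.

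List medians that turned sign were (with the range over left-out libraries), with library totals, skeletal muscle in RT_FAP41BBL against FAP41BBL (-0.007), and with the 2 groups alone, epithelial tumour cells in FAP41BBL against control (-0.073). Without 1 library, skeletal muscle in RT_FAP41BBL against FAP41BBL was -0.235, -0.39, -0.112 and -0.159 without FAP41BBL replicate 1 and 2 and RT_FAP41BBL replicate 1 and 2, and up to 1.841. In FAP41BBL against control, epithelial genes were -0.095, -0.084 and -0.093 without FAP41BBL replicate 3 and control replicate 1 and 3, and up to 1.983, and endothelial and muscle genes -0.083 and -0.865 without FAP41BBL replicate 3, and up to 0.26 and 1.431. Keratinocyte genes in RT against control were 0.421 without control replicate 2, and down to -9.678. Epithelial genes in RT_FAP41BBL were 2.382 and 0.27 against control without control replicate 2 and RT_FAP41BBL replicate 2, and down to -0.355, and -0.464 against FAP41BBL without RT_FAP41BBL replicate 3, and up to 0.415. Against RT, type I interferon genes were -0.154 without RT_FAP41BBL replicate 2 (up to 0.253), immediate early genes 0.002 without RT replicate 1 (down to -0.202) and neutrophil genes 0.477 without RT replicate 3 (down to -0.225). Fibroblast genes had an interaction of 0.312 without FAP41BBL replicate 3, and down to -0.25. With the muscle covariate, in RT against control, Ckmt2 was -0.317 and Tmem233 -1.209, fibroblasts -0.371, TGF-beta targets 0.44 and endothelial cells -0.475. Under it, RT_FAP41BBL against RT had type I interferon genes at -0.142 and neutrophils at 0.94, and the interaction had neutrophils at 0.773 and fibroblasts at 0.356.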

Other observations

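The sterol and muscle lists in this part, and the tests of explanations for Per1, were chosen after the results were seen, while the splits of the libraries were planned. Genes of sterol synthesis, 22 enzymes and regulators of the cholesterol pathway, were lower in the irradiated groups. In RT 16 of 22 fell against control, with a median of -0.96, and in RT_FAP41BBL 19 of 22 fell, with a median of -1.21. Srebf2, which encodes the transcription factor that drives the pathway, stood at 247 ± 21.5 CPM in control, 114 ± 11.2 in RT, 200 ± 44.5 in FAP41BBL and 102 ± 16 in RT_FAP41BBL. Fdps, an enzyme of isoprenoid synthesis, stood at 125 ± 13.1, 37.8 ± 10.8, 94.9 ± 61.7 and 32.3 ± 5.71 CPM. FAP41BBL had no member past the threshold and a median of -0.23. The list was put together after some of its members had been seen among the largest falls, so these counts describe the pattern and do not test it. Fdps lost its call in all 6 fits that left out a library for RT against control and in 5 of 6 for RT_FAP41BBL, with adjusted p-values of up to 0.0833 and 0.0926. Against FAP41BBL, 8 of 22 genes fell in RT_FAP41BBL, and the interaction median was 0.04. Without FAP41BBL replicate 1, in which Fdps stood at 164 CPM against 44.2 and 77.0 in the other FAP41BBL libraries, 0 genes passed by edgeR in that comparison, where 2398 had an unadjusted p under 0.05 and 783 passed with DESeq2 with all libraries. Of the 6 fits that left out a library, Cyp51, Fdft1, Hmgcs1 and Insig1 lost their calls in 5 and Sqle and Srebf2 in 4. Abcg1, a cholesterol exporter, stood at 51.6 ± 6.05, 119 ± 49.6, 85.1 ± 34 and 268 ± 31.4 CPM in control, RT, FAP41BBL and RT_FAP41BBL, and was named after its values were seen. Its call in RT was lost in 5 of 6 such fits.

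Genes of slow and developing muscle fibres were a second such list. Of 11 genes 10 rose in RT against control, with a median of 4.14, and 1 rose in RT_FAP41BBL, with a median of 1.77. Myog, a transcription factor of muscle differentiation, stood at 0.724 ± 0.839 CPM in control, 6.12 ± 1.03 in RT, 0.616 ± 0.374 in FAP41BBL and 2.19 ± 1.05 in RT_FAP41BBL. Its call in RT was lost in 4 of 6 fits that left out a library.

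Per1 was lower in each treated group than in control. If harvest at another time of day were the cause, the other core clock genes would move with Per1. Their median absolute change in FAP41BBL against control was 0.33, and they shifted as a set (unadjusted p = 0.00979 by camera with an estimated correlation). Only 1 of 13 lay below 0, so most rose while Per1 fell. From control to FAP41BBL, Per2 went from 23.1 ± 3.81 to 26.2 ± 4.99 CPM, Dbp from 11.1 ± 1.56 to 17.3 ± 7.09 and Nr1d1 from 27 ± 8.12 to 35.2 ± 14.2. The bound that would exclude this explanation was tightened after that shift was seen, so the explanation cannot be told apart from a treatment effect without harvest times. Lower glucocorticoid signalling would lower other glucocorticoid-induced genes, which had a median of -0.32 in FAP41BBL (unadjusted p = 0.00598 with an estimated correlation), but 0.209 in RT, with 2 of 17 higher and 3 lower, and 0.012 in RT_FAP41BBL, with 1 higher and 4 lower. Tsc22d3 and Arrdc2, glucocorticoid-induced genes chosen after their values were seen, had lower means in each treated group. They stood at 137 and 38.8 CPM in control. In RT, FAP41BBL and RT_FAP41BBL Tsc22d3 stood at 84.4, 56.6 and 59.9 CPM and Arrdc2 at 14.1, 19.2 and 16.4. Of the 17 genes only 8 lay below 0 in each irradiated group. Members that went both ways decide nothing in the irradiated groups, so this explanation stays open too, and both explanations may hold for part of the pattern.

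Other splits of the 6 libraries of each pairwise comparison gave fewer genes than the real groups. For RT against control the real split gave 1709 genes and the highest other 0, for FAP41BBL 1 and 0, for RT_FAP41BBL 1404 and 1, for RT_FAP41BBL against RT 1022 and 0, and against FAP41BBL 168 and 0, so that 1 of 10 splits reached the real count in each. For the lists, 5 of 10 splits gave as many for RT against control (16 real, highest other 20), 1 for FAP41BBL (21 and 19), 6 for RT_FAP41BBL (18 and 22), 6 for RT_FAP41BBL against RT (16 and 20) and 6 against FAP41BBL (14 and 16). With 10 splits, the splits are too few for a share under 0.05.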
